A study of Mus musculus with 4 samples.

How the data were processed

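The study measured RNA of sorted basal mammary cells in 4 libraries, 2 from wild-type (WT) outgrowths and 2 from outgrowths of miR-205-floxed cells treated with Cre (KO). Per the labels' protocols, total RNA was extracted with a PicoPure kit, made for small numbers of cells, and libraries were prepared with NuGEN RNA-Seq and Illumina protocols. The deposited values are whole-number read counts per Ensembl gene, 1 file per library. The submitters' processing notes name TopHat2 (2.02) for alignment, HTSeq for counting, and the NCBIM37 (mm9) build. The annotation release, the strand setting and the rule for overlapping genes are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart, and genes with near-identical copies, such as the Serpina3 cluster and the Hspa1a pair, have uncertain counts.

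Each file held 34615 gene rows and 5 summary rows, which stayed out of library sizes and tests. Reads outside any feature were 61.4% and 57.59% of all counted lines in WT and 57.85% and 61.52% in KO, and ambiguous reads 0.72% and 0.79% in WT and 0.77% and 0.71% in KO. Symbols, biotypes, G+C content and 3' UTRs came from GENCODE M21, a GRCm38 annotation, matched on gene identifiers: 30082 rows matched (86.9%, holding 98.6% of the counts). That annotation is of a later build than the counts, so gene coordinates are not given, except those of the Mir205 hairpin, which was matched by its mature sequence in GRCm38. Mitochondrial genes and nearly all chromosome 11 genes, among them Krt14, Krt17, Axin2 and Egfr, were not analysed here.

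Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with default settings, TMM scaling, and the quasi-likelihood test of KO against WT with genotype as the term and no replicate block. Benjamini-Hochberg adjusted p-values under 0.05 over all tested genes were called. Fold changes are log2 of KO over WT from the edgeR fit at its default prior count, so those of genes near 0 counts can be very large. Values per library are CPM scaled by TMM. A set of 33 gene lists with 591 entries, 522 of which matched a row, was tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, over lists with 5 or more tested members, and again with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the libraries, and with 2 per group almost no list could pass. A call lost there is therefore no evidence that correlation between genes produced it, and does not exclude it either. Genes with a miR-205-5p site were tested with camera among protein-coding genes with an annotated 3' UTR. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

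The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule named 14 genes in advance, the 12 genes per direction with the largest change among called genes, the 3 members with the smallest p in each called list, and up to 2 called members of other lists. With fewer than 5 called genes in a direction, the 5 protein-coding genes with the smallest p at a mean CPM of 5 or more were named. Predicted genes, Rik clones and pseudogenes were passed over, which included Ftl1-ps1, typed as protein-coding but named as a pseudogene. Genes named outside the rule are stated in the text as chosen after their values were seen. Gene lists were built from general knowledge, and none was chosen on these libraries.

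Alternatives tried were DESeq2 (1.42.0) size factors and its Wald test, upper quartile and total count scaling, no low-count filter, a mean CPM of 5 or more, limma voom, a G+C offset (values for 94.3% of tested genes), a replicate block, a test against a 1.5-fold change, and each library left out in turn. With a library left out, the lone library of its group is assumed to vary like the others. A mean CPM of 50 or more, library quality weights, matched random lists and the site ranking without KO replicate 2 were added after seeing the data. The procedure was tested on simulated counts, drawn independently for each gene with the same spread in every library. Changed genes and lists were taken at a mean CPM of 5 or more. The simulation held no correlated genes and no library like KO replicate 2, so it cannot test camera or recovery under those conditions. With the spread of the 4 libraries (14120 genes), 2%, 32%, 48% and 80% of genes changed 2, 4, 8 and 16 times were recovered, and camera called 0 of 20 unchanged lists. With the spread without KO replicate 2 (1 KO against 2 WT, 16176 genes), the shares were 32%, 76%, 90% and 94%, and camera called 1 of 20 unchanged lists.

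Gene counts per library ran from 47953972 to 60030932. A count of 0 allows up to 3 counts, or 0.04997 to 0.06256 CPM. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The biological coefficient of variation was 0.932 with 4 libraries, 0.6079 without KO replicate 2 and 0.6037 without KO replicate 1. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 91.1 for the WT pair and 503.9 for the KO pair.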

Results

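Gene expression was measured by RNA sequencing in basal cells of the mouse mammary gland, the outer cell layer that holds myoepithelial cells and cells able to regrow a gland. Mammary cells carried either wild-type miR-205 alleles (WT) or alleles of this microRNA flanked by loxP sites (KO). A Cre adenovirus removed the floxed alleles and switched a membrane reporter from red to green, and the cells were transplanted into SCID-Beige mice aged 3 weeks. After 8 weeks, cells from a pool of 40 outgrowths were sorted for green fluorescence, CD24 and high CD49f. The comparison addressed which genes differ when basal cells lack miR-205, with YAP and Wnt signaling named in the title of the series. There were 2 WT and 2 KO libraries, with 53067076 and 57650462 gene counts in WT and 60030932 and 47953972 in KO.

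Basal markers were abundant in all 4 libraries. Krt5, the basal keratin, stood at 1219 ± 0.33 counts-per-million (CPM; mean ± SD, n = 2) in WT and 1642 ± 185 CPM in KO. Trp63, the transcription factor of the basal lineage, stood at 976 ± 102.5 and 1105 ± 288.5 CPM. Acta2, smooth muscle actin of myoepithelial cells, had a mean of 2699 CPM over the 4 libraries, and the luminal keratin Krt8 had 311.5 CPM. Of the luminal progenitor markers, Plet1 and Lcn2 had means of 1418 and 1185 CPM, above Trp63 at 1040 CPM. Genes were seen less often in KO replicate 2: 12679 genes had a count there, against 18139 and 18027 in the WT libraries and 18897 in KO replicate 1. Among genes at 1 to 5 CPM in WT, 41.5% had no count in KO replicate 2, against 0.59% in KO replicate 1. Correlations of log2 CPM across genes, which are not independent replicates, were 0.715 to 0.73 between KO replicate 2 and each other library. They were 0.961 for the WT pair, and 0.972 and 0.968 between KO replicate 1 and WT replicates 1 and 2. By this measure KO replicate 1 lay no further from WT than the WT libraries lay from each other.

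**Figure D1:**
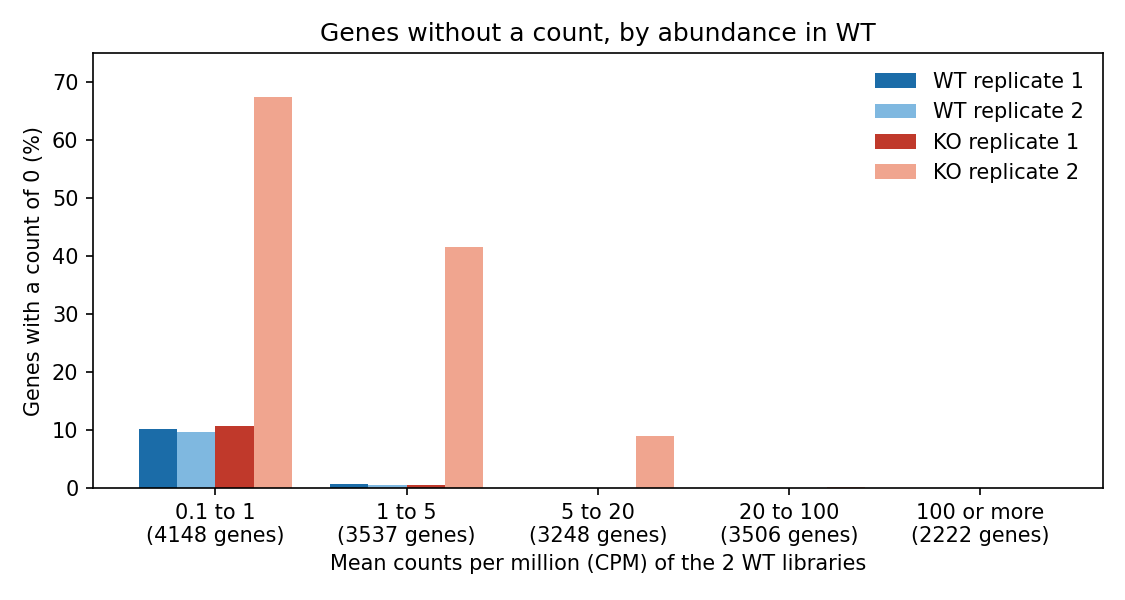
Share of genes with a count of 0 in each library (vertical axis, percent), grouped by the mean CPM of the gene in the 2 WT libraries (horizontal axis, with the number of genes in each group). KO replicate 2 stands above the other 3 libraries up to 20 CPM, with 67.4% of genes at 0 between 0.1 and 1 CPM and 8.96% between 5 and 20 CPM.

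The targeted gene gave no check of the labels. Mir205 (ENSMUSG00000065533), whose hairpin of 68 bases is annotated on chromosome 1 from 193507463 to 193507530 on the minus strand in GRCm38, had 0 counts in each of the 4 libraries. A count of 0 allows up to 0.05653 and 0.05204 CPM in WT and up to 0.04997 and 0.06256 CPM in KO, for counting error only. Its host transcript Mir205hg was not analysed here. The groups below therefore rest on the sample labels.

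Single genes that stood furthest apart between KO and WT, relative to their spread, included a collagen receptor and a protease inhibitor lower in KO and a growth factor higher in KO. Itga2 (ENSMUSG00000015533), the integrin alpha 2 chain that binds collagen, stood at 294.4 ± 27.05 CPM in WT and 129.4 ± 3.73 CPM in KO, a log2 fold change of -1.19 ± 0.21 (SE). Serpina3n (ENSMUSG00000021091), a secreted serine protease inhibitor, stood at 123.4 ± 38.2 CPM in WT and 31.3 ± 4.79 CPM in KO (log2 fold change -1.98 ± 0.36). Fgf1 (ENSMUSG00000036585), a fibroblast growth factor, stood at 129.5 ± 1.91 CPM in WT and 214.6 ± 1.36 CPM in KO (log2 fold change 0.73 ± 0.21). None of these differences passed the test over all genes.

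Of 15364 genes tested with the edgeR quasi-likelihood test, 0 were higher and 0 were lower in KO at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.9989. At an unadjusted p under 0.05 there were 147 genes, 91 higher and 56 lower in KO, where chance would give 768. DESeq2 called 4 genes and limma voom called 0. The DESeq2 calls were Serpina3n, lower in KO with an adjusted p of 0.01455 (0.00494 to 1 over the other settings), and Emc9, Arl2 and 2810408I11Rik, higher in KO. Emc9 had 4 and 3 counts in WT, 14 in KO replicate 1 and 2366 in KO replicate 2, and Arl2 had 100 and 37 counts in WT, 167 in KO replicate 1 and 6318 in KO replicate 2. KO and WT did not overlap in 4982 genes (32.4%), where chance gives 33.3%. Without KO replicate 1, 2036 genes were called higher and 3688 lower, and without KO replicate 2 the counts were 0 and 0. Leaving out WT replicate 1 or WT replicate 2 gave 5 genes higher in KO each time, among them Arl2 and Csf3r. Without KO replicate 1 the only KO library was KO replicate 2, so those calls cannot be told apart from the low detection in that library. Nothing states that the replicates of a genotype came from separate animals or pools. The p-values therefore measure the spread between these libraries, which may be technical.

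Genes with the smallest p-values were named in each direction as not past the threshold. On the lower side of KO, after Itga2 and Serpina3n, came Myo9b (ENSMUSG00000004677), an unconventional myosin, with 166.5 ± 6.15 CPM in WT and 88.2 ± 19.3 in KO. Las1l (ENSMUSG00000057421), a factor of ribosomal RNA processing, had 100.4 ± 3.97 CPM in WT and 54.6 ± 4.01 in KO. Cars (ENSMUSG00000010755), the cysteinyl-tRNA synthetase, had 124.3 ± 11.0 CPM in WT and 73.8 ± 2.35 in KO. On the higher side, Etnk1 (ENSMUSG00000030275), an ethanolamine kinase, had 182.4 ± 6.66 CPM in WT and 398.6 ± 123.6 in KO. Ptprj (ENSMUSG00000025314), a receptor tyrosine phosphatase, had 178.4 ± 2.46 and 340.5 ± 96.96 CPM, and Ttc9 (ENSMUSG00000042734) had 46.4 ± 16.5 and 166.3 ± 92.9 CPM. Fam149a (ENSMUSG00000070044) had the widest fitted difference of these 5, a log2 fold change of 3.78 ± 1.08, with 8.75 CPM in KO replicate 1 and 55.1 CPM in KO replicate 2. All 10 genes had both KO libraries on the same side of both WT libraries, and the unadjusted p-values of the edgeR test ran from 0.00232 for Itga2 to 0.02994 for Cars.

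**Figure D2:**
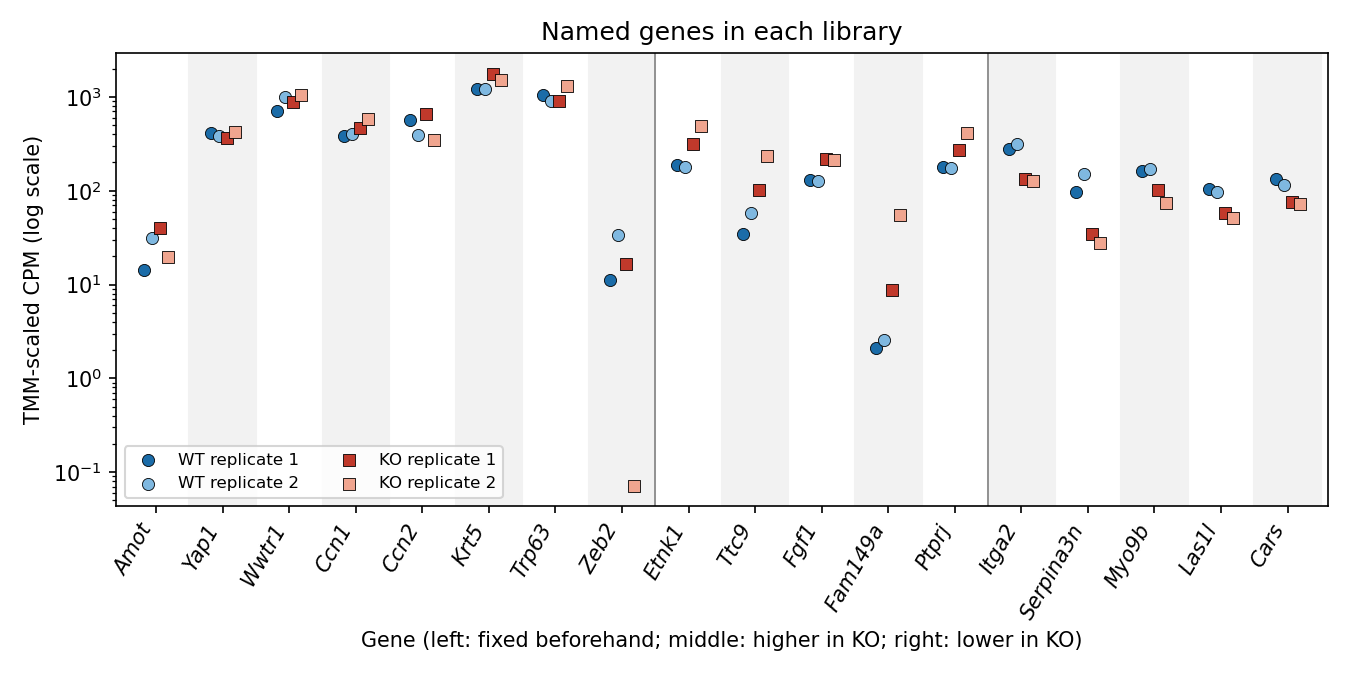
CPM scaled by TMM (vertical axis, log scale) of genes named beforehand (left), of the 5 genes with the smallest p higher in KO (middle) and of the 5 lower in KO (right), 1 point per library. Fgf1 sat at 215.6 and 213.7 CPM in the KO libraries and at 130.8 and 128.1 CPM in WT, while Yap1 overlapped between the groups.

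YAP/TAZ target genes, transcripts commonly induced by the Hippo pathway effectors YAP and TAZ, were higher in KO as a list by camera (adjusted p = 0.0088), a call that was lost with an estimated correlation (adjusted p = 0.8367). Of 20 measured members, 16 had a positive fold change, 0 passed the test over all genes and 0 passed adjusted over the list alone. The median log2 fold change was 0.32, at percentile 97.6 of random lists of like abundance, which had a median of 0.09. With 4 libraries abundance could therefore not be told apart from a list effect. Ptpn14, a phosphatase that binds YAP, had 253 ± 11.98 CPM in WT and 377.5 ± 67.6 in KO. Tgfb2 had 112 ± 3.0 and 201 ± 94.2 CPM, and Amotl2, an angiomotin-family member, had 25.8 ± 0.37 and 45.2 ± 6.85 CPM. The matricellular protein genes Ccn1 and Ccn2 had log2 fold changes of 0.42 ± 0.20 and 0.06 ± 0.39. The call also ended without WT replicate 2 (adjusted p of 0.05135), without KO replicate 1 (0.0723), with fry (0.7974) and at a mean CPM of 50 or more (0.1727), a limit added after seeing the data. Its median stood at 0.17 in KO replicate 1 and 0.53 in KO replicate 2, the library with fewer genes detected, relative to the WT mean.

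The effectors themselves did not part the genotypes. Yap1 stood at 398.7 ± 24.0 CPM in WT and 395 ± 38.95 in KO, and Wwtr1, which encodes TAZ, stood at 848.3 ± 202.4 and 963.4 ± 118 CPM. Amot, an angiomotin that binds YAP, had 22.6 ± 11.9 CPM in WT and 29.6 ± 14.3 in KO, with overlapping libraries. Among 21 measured Hippo pathway components, 10 fold changes were positive and 11 negative, with a camera adjusted p of 0.4328 (test direction up, median just below 0). The most abundant of them, Fat1, had a log2 fold change of 0.00 ± 0.23, and Amotl1 had 0.10 ± 0.19.

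Immediate early and stress genes, which cells induce within minutes of handling, were higher in KO as a list by camera (adjusted p = 0.0088), a call that was lost with an estimated correlation (adjusted p = 0.8367). Of 24 measured members 18 were positive, the median was 0.19, at percentile 80.72 of random lists of like abundance, and 0 passed over all genes or adjusted over the list alone. Fos had 449.3 ± 17.4 CPM in WT and 665.1 ± 155.2 in KO, Dusp1 had 814.6 ± 49.6 and 1333 ± 524.8 CPM, and the heat shock gene Hspa1a had 33.6 ± 0.53 CPM in WT, 38.8 CPM in KO replicate 1 and 145.8 CPM in KO replicate 2. The adjusted p of this list was 0.102 without WT replicate 1, 0.0723 without KO replicate 1 and 0.1169 at a mean CPM of 5 or more. Basement membrane and integrin genes had a camera adjusted p = 0.03371, also lost with an estimated correlation (adjusted p = 0.8367). They had 17 of 20 positive members and a median of 0.22, at percentile 85.64 of random lists of like abundance, again with 0 passing over all genes or adjusted over the list alone. Hspg2, which encodes perlecan, had 690 ± 57.2 CPM in WT and 820.5 ± 7.76 in KO. Itga9 had 144.7 ± 8.09 CPM in WT, 149 CPM in KO replicate 1 and 233 CPM in KO replicate 2. The collagen gene Col4a6 had 112.1 ± 1.04 CPM in WT, 106.4 CPM in KO replicate 1 and 215.9 CPM in KO replicate 2. The adjusted p of these genes was 0.292 without WT replicate 1, 0.07688 without KO replicate 1, 0.8074 without KO replicate 2 and 0.3482 at a mean CPM of 5 or more. Without KO replicate 1 none of the 31 lists was called, and KO replicate 2 is the library with fewer genes detected.

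Wnt pathway genes were not called in any of 3 lists. Among 15 Wnt/beta-catenin target genes, 8 fold changes were positive and 7 negative (camera adjusted p of 0.6451, test direction up, median 0.04, mean -0.23). Lgr5, a stem cell receptor, had 112.8 and 74.1 CPM in WT and 89.5 and 258 CPM in KO, and Procr had 47.0 and 129.3 CPM in WT and 58.2 and 35.0 CPM in KO. Lef1 was near the floor, with 9 and 82 counts in WT and 25 and 0 in KO, and Axin2 was not analysed here. Among 11 Wnt ligands, 3 were positive (camera adjusted p of 0.6341, median -0.57). The ligand median stood at -1.18 in KO replicate 2 and -0.01 in KO replicate 1. Log2 fold changes were 0.88 ± 0.53 for Wnt5a, 1.17 ± 0.59 for Wnt10a and -0.86 ± 0.60 for Wnt5b. Wnt5a had 52.5 and 64.2 CPM in WT, 57.6 CPM in KO replicate 1 and 157 CPM in KO replicate 2. Wnt10a had 15.1 and 12.7 CPM in WT, 19.8 CPM in KO replicate 1 and 42.8 CPM in KO replicate 2. Among 23 receptors and secreted modulators, 13 were positive (adjusted p of 0.3046, median 0.04). In that list Fzd7 had a log2 fold change of 0.50 ± 0.22 and Fzd1 one of -0.78 ± 0.32. The Wnt members given with values, except Lef1 and Axin2, were chosen after their values were seen.

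Genes published as miR-205 targets showed no common direction, with 8 of 14 positive (adjusted p of 0.599, median 0.14, mean -0.03). Lrp1, an endocytic receptor, had a log2 fold change of 0.55 ± 0.27. Zeb2, an inducer of epithelial to mesenchymal transition, had 11.3 and 33.4 CPM in WT and 16.6 and 0.07 CPM in KO. Zeb1 had 8 counts in WT replicate 2 and 0 in each other library, and was not tested. In the wider set, 1527 of 12616 protein-coding genes carried a 7mer-m8 (ATGAAGG) or 8mer (ATGAAGGA) match to miR-205-5p in the longest annotated 3' UTR. Their median log2 fold change was 0.00, against -0.13 for genes without a site, and limma camera gave a p of 0.09817 (direction up). Among 3519 other sequences of 7 bases with the same G+C and CpG content, this difference of 0.13 lay at percentile 96.6, while the median of those others was 0.08. Without KO replicate 2 the difference was 0.02, with a camera p of 0.853 and a percentile of 98.5.

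Basal identity markers went both ways, with 7 of 14 positive (adjusted p of 0.5288, test direction up, median -0.01). Itga6, which encodes the sorted antigen CD49f, had a log2 fold change of 0.28 ± 0.17, and Col17a1, a hemidesmosome collagen, had -0.31 ± 0.17. Krt14 was not analysed here. Contractile myoepithelial genes were split likewise, 6 of 13 positive (adjusted p of 0.6805, test direction up, median and mean both -0.01), with Acta2 at 3707 CPM in KO replicate 1 and 2264 CPM in KO replicate 2. The list median stood at 0.25 in KO replicate 1 and -0.37 in KO replicate 2, and without KO replicate 2 the list had 12 of 13 positive members (camera adjusted p = 0.001067, and adjusted p = 0.9585 with an estimated correlation). Luminal progenitor markers had 8 of 13 negative members and a median of -1.12 (adjusted p of 0.1119, and 0.01178 without WT replicate 1, 0.001067 without KO replicate 2, 0.9612 without WT replicate 2 and 0.8367 with an estimated correlation), -0.61 in KO replicate 1 and -1.21 in KO replicate 2 relative to WT, and Itga2 was the 1 member that passed adjusted over the list alone. Kit had 15.6 and 27.6 CPM in WT and 6.91 and 1.44 CPM in KO, while Lcn2 had 926 and 1102 CPM in WT and 1255 and 1457 CPM in KO. Pan-luminal markers were 7 of 12 positive (adjusted p of 0.5879), mammary stem cell-associated genes 7 of 12 (0.3046), hormone-sensing luminal markers 5 of 12 (0.9093, test direction up, median -0.29) and milk genes 6 of 9 (0.599). Without KO replicate 2 the milk list turned lower, with 7 of 9 negative and a median of -0.98 (camera adjusted p = 0.01046, and adjusted p = 0.9585 with an estimated correlation). The examples Plet1, Itga6, Col17a1, Acta2, Krt8, Kit and Lcn2, like Lrp1, Fat1, Amotl1, Csf3r and the genes called by DESeq2 other than Serpina3n, were chosen after their values were seen.

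Markers of cells outside the gate were measured in both genotypes. Endothelial markers had 1 of 13 positive members (camera adjusted p of 0.3046), led by Cdh5 at a mean of 64.3 CPM. Immune markers had 6 of 13 (0.6341), led by Cd74 at 56.1 and 136.4 CPM in WT and 71.9 and 289.2 CPM in KO. Fibroblast markers had 7 of 13 (0.4328), led by Fbn1 at a mean of 419.2 CPM, above Krt8, and with both KO libraries above both WT libraries in 3 members and below them in 3. Of the 13 fibroblast markers, 2 had an unadjusted p under 0.05 in the edgeR test, and neither passed over all genes. Dcn, which encodes decorin, had 89.5 and 105.6 CPM in WT and 153.2 and 221.3 CPM in KO, and Col6a1, a collagen VI gene, had 47.2 and 46.4 CPM in WT and 75.6 and 131.9 CPM in KO. Pericyte markers had 4 of 8 (0.9093) and adipocyte markers 1 of 6 (0.9093), with Fabp4 at 14.8 and 28.3 CPM in WT and 32.2 and 138.8 CPM in KO. These marker genes were chosen after their values were seen. Red blood cell genes and skeletal muscle and nerve markers had 3 and 4 tested members and were not tested as lists. Keratinocyte differentiation genes had 4 of 8 positive members (0.617), EMT-associated genes 8 of 14 (0.599) and cell polarity and junction genes 11 of 17 (0.6341). In the fibroblast, keratinocyte, EMT and polarity lists the mean fold change was negative while the median and the test direction were positive. Ribosomal protein genes took 1.488% and 1.313% of gene counts in WT and 1.473% and 1.233% in KO. That difference in mean share, -0.047 percentage points, lay within the SD of either group, and an exact permutation test of these groups cannot go below 0.333.

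**Figure D3:**
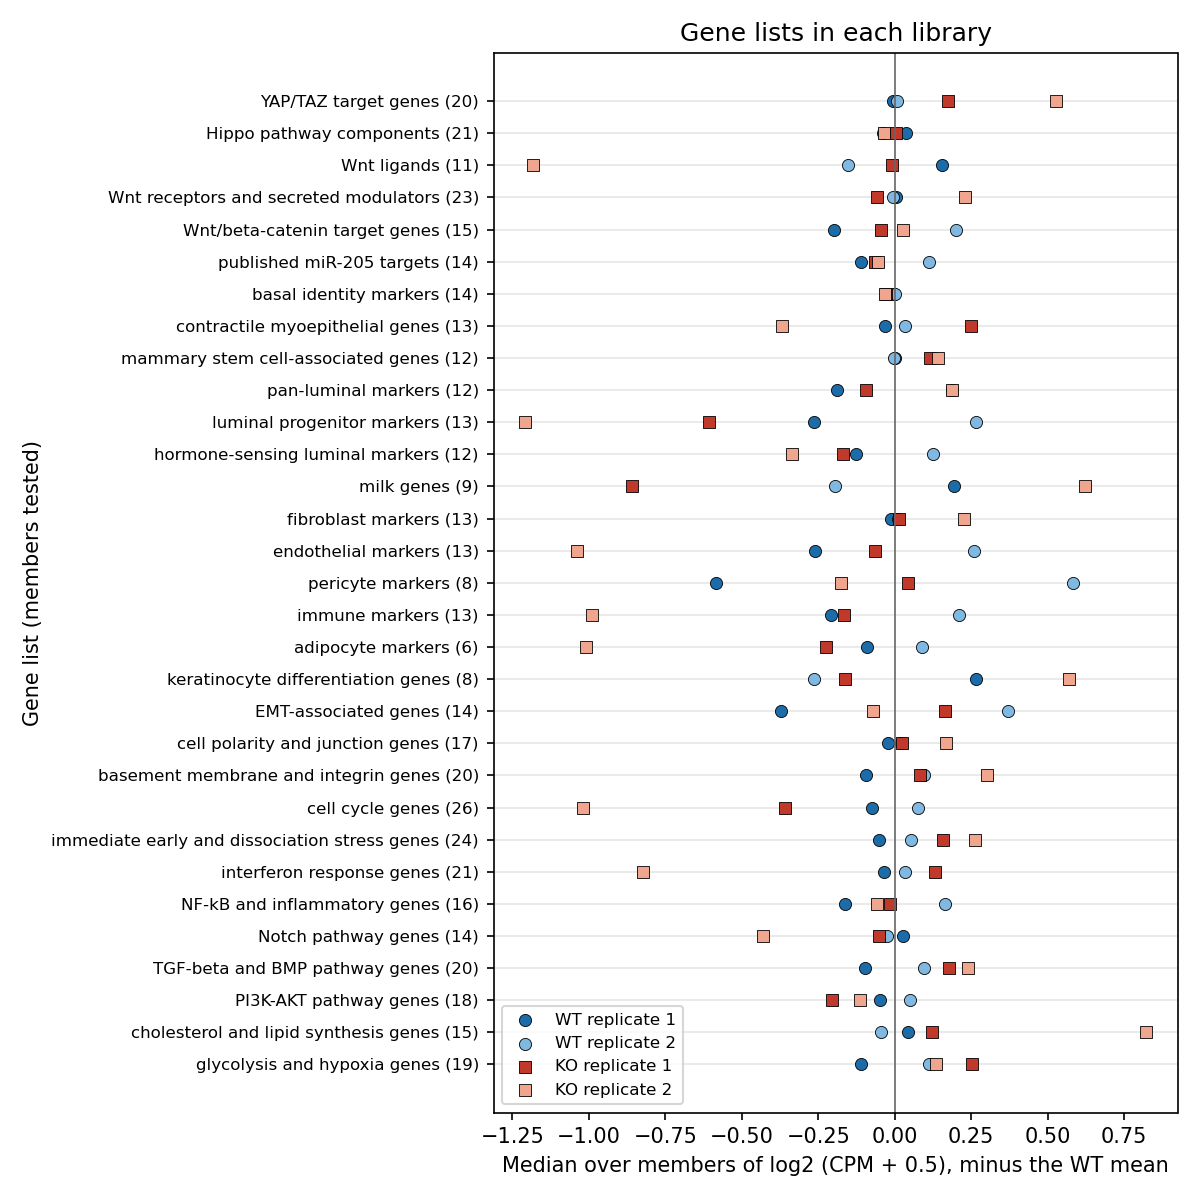
Median over the members of each gene list of log2 (CPM + 0.5), minus the mean of the WT libraries (horizontal axis), 1 point per library, with the number of members tested in parentheses. The YAP/TAZ target list stood at 0.17 and 0.53 in KO, while lists of low abundance such as endothelial markers (-1.04) and cell cycle genes (-1.02) lay low in KO replicate 2.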

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

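The count of 0 called genes held under every scaling, filter, G+C, voom, quality-weight and 1.5-fold setting, and also with the replicate block, where 79 genes had p under 0.05 and 0 were called. Deviations of same-numbered libraries correlated at 0.01. That cannot exclude a pairing, since KO replicate 2 dominated the KO deviations (SD of the log2 difference 2.03 in the KO pair, 0.56 in the WT pair). DESeq2 called 4 genes, 3 higher and 1 lower. Without KO replicate 1 the only KO library was KO replicate 2. Genes called in that setting therefore cannot be told apart from the low detection and wide scatter of that library. Leaving out 1 library gave 0 to 5724 called genes, 0 to 2036 higher and 0 to 3688 lower; the highest counts came without KO replicate 1, 5 higher when either WT library was left out, and 0 without KO replicate 2. The cause was not tested.

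Of the 28 named genes under settings that keep all libraries, 352 of 358 values had the same direction and side of the threshold, 1 was past it (Serpina3n, DESeq2) and 5 reversed, all near 0: Yap1 with the G+C offset (0.11) and with block and offset (0.094), and Ccn2 with upper quartile (-0.013) and total count scaling (-0.027) and at a mean CPM of 50 or more (-0.02). Leaving out a library reversed 10 of 112 values. Values passed the threshold only without KO replicate 1, where KO replicate 2 was the only KO library. Without KO replicate 2, 26 of 28 kept their direction. Ranges with a reversal were Amot -0.22 to 1.06, Yap1 -0.12 to 0.08, Wwtr1 -0.044 to 0.45, Ccn2 -0.49 to 0.46, Trp63 -0.11 to 0.42, Lef1 -8.35 to 0.32 and Col4a6 -0.073 to 0.94. Wide ranges without one were Hspa1a 0.21 to 2.11, Itga9 0.045 to 0.68, Dusp1 0.24 to 1.06, Tgfb2 0.27 to 1.25, Fos 0.31 to 0.78, Ccn1 0.26 to 0.56, Hspg2 0.17 to 0.34, Ptprj 0.61 to 1.19, Ttc9 1.12 to 2.32, Fam149a 1.91 to 4.56 and Zeb2 -8.24 to -0.43. The cause was not tested.

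Of gene lists, 3 were called, also with the replicate block; 0 were with an estimated correlation, fry or a mean CPM of 50 or more, 1 at 5 or more, and 0 to 5 with a library left out. Adjusted p was 0.8367 with an estimated correlation and 0.7974 with fry for YAP/TAZ targets, basement membrane and immediate early genes alike. For immediate early genes the estimated correlation was 0.001764, below the preset 0.01, yet the unadjusted camera p rose from 0.0005678 to 0.0644. For that list the loss therefore reflects the few libraries more than correlation between genes. The estimated correlation was 0.1723 for basement membrane genes and 0.04488 for YAP/TAZ targets, above the preset. For these lists correlation stays open as a part of the loss. At a mean CPM of 5 or more the camera adjusted p was 0.3482 for basement membrane and 0.1169 for immediate early genes. At 50 or more it was 0.1727 for YAP/TAZ targets, 0.7015 for basement membrane and 0.452 for immediate early genes. Leaving out a library gave 0.01178 to 0.0723 for YAP/TAZ targets (not called without KO replicate 1 or WT replicate 2), 0.02516 to 0.8074 for basement membrane and 0.02516 to 0.102 for immediate early genes. Fewer genes are tested under the CPM limits; the other causes were not tested. Sites of miR-205 had p 0.08567 to 0.1796 under other settings and 0.1121 to 0.853 with a library left out, never called. The ribosomal share difference ran from -0.167 to 0.073 percentage points. At these depths a count of 0 allows 0.04997 to 0.06256 CPM.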

Other observations

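Of the tests and settings below, the matched random lists were chosen after the list results they examine were seen, as was the Serpina3 cluster after its values. The limits of all tests were written before the deciding values were computed, when the number of genes detected and the total of each library were already known. Parts of the decision rules came after the values were seen. The sampling margin of the percentiles and the condition of a lower median each changed an outcome to undecided. The Wilson interval changed none.

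Without KO replicate 2, 1 KO library stood against 2 WT libraries. The lists below were called by camera in that setting, and none held with an estimated correlation. With so few libraries almost no list could pass that second test, so failing it decides little. Correlation between genes stays open as a source of these calls. With 4 libraries it was estimated at 0.4469 for contractile, 0.2279 for milk and 0.1933 for luminal progenitor genes. All were above the preset 0.01, so camera p-values at the preset may be too small. Luminal progenitor markers had 12 of 13 members negative (median -0.83, camera adjusted p 0.001067, and 0.9585 with an estimated correlation), and milk genes 7 of 9 (median -0.98, 0.01046 and 0.9585). Contractile myoepithelial genes had 12 of 13 positive (median 0.24, 0.001067 and 0.9585), with Acta2 at 3707 CPM in KO replicate 1 against 2493 and 2331 CPM in WT. YAP/TAZ targets and immediate early genes were called too, both in the upward direction, with medians of 0.26 (21 members) and 0.16 (24 members). The 20 YAP/TAZ members also tested with 4 libraries had a median of 0.18. The percentiles of that list given below rest on those 20. In KO replicate 2 the contractile list lay at -0.37 and milk genes at 0.62 relative to WT, opposite to 0.25 and -0.86 in KO replicate 1, while luminal progenitor markers lay low in both (-0.61 and -1.21). Elf5, a transcription factor of luminal progenitors, had 3.05 and 4.79 CPM in WT and 1.496 and 0 CPM in KO.

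With all 4 libraries, metabolic and signaling lists came near the threshold at the preset correlation without passing it. For the glycolysis, cholesterol and TGF-beta lists alike, the camera adjusted p was 0.8367 with an estimated correlation, and the fry adjusted p was 0.7974. Glycolysis and hypoxia genes had 10 of 19 positive members (camera adjusted p 0.05983), with Ldha at 469.1 and 479.1 CPM in WT and 650.4 and 739 CPM in KO. Cholesterol and lipid synthesis genes had 9 of 15 (0.05815), with a list median of 0.12 in KO replicate 1 and 0.82 in KO replicate 2 relative to WT. TGF-beta and BMP pathway genes had 14 of 20 (0.05815), with the activin antagonist Fst at 608.9 and 696 CPM in WT and 823.1 and 1106 CPM in KO. Cell cycle genes had 7 of 26 positive (0.4936), and Mki67, the proliferation antigen, had 53.9 and 69.1 CPM in WT and 30.9 and 31.3 CPM in KO. Interferon response genes (9 of 21, 0.5613), NF-kB and inflammatory genes (6 of 16, 0.5879, median -0.07 with the test direction up), Notch pathway genes (8 of 14, 0.9873, mean -0.52 with the test direction up) and PI3K-AKT pathway genes (6 of 18, 0.963, median -0.14 with the test direction up) were not called. These genes were chosen after their values were seen.

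KO replicate 2 detected 12679 genes. Sequencing depth is argued against: the other libraries, thinned to its total, still detected at least 1.41 times as many genes. Loss of miR-205 as the whole cause is argued against too. There were 1152 genes at 1 CPM or more in both WT libraries and 0 in KO replicate 2. Of these, 8.16% (Wilson 95% interval 6.71 to 9.88%) lay below 25% of WT in KO replicate 1, under the 10% set beforehand. Among all genes at that level in WT the share was 1.34%, but these were not matched on abundance. At 1 to 5 CPM in WT, KO replicate 2 had 0 counts for 41.5% of genes, and at 20 to 100 CPM for 0.17%. The log2 ratio of KO replicate 1 to WT had an SD of 1.146 at 1 to 5 CPM and 0.2457 at 100 or more. A part shared by both KO libraries therefore cannot be told apart from scatter at low counts, and stays open. Transcript loss from a small RNA input was to show as over 10% of genes at 5 to 20 CPM with 0 counts, and the share was 8.96% (291 of 3248, Wilson 95% interval 8.02 to 9.99%), a narrow miss; the interval was added to the rule after the value was seen and did not change its outcome. On the other side stand 41.5% at 0 between 1 and 5 CPM and 0.03% in KO replicate 1 between 5 and 20 CPM. The second condition separated nothing (SD ratio 4.44 in KO replicate 2, 4.66 in KO replicate 1). The SD itself differed: at 5 to 20 CPM the log2 ratio to WT had an SD of 2.59 in KO replicate 2 and 0.58 in KO replicate 1. In that range 4.4% and 0.0% of genes stood over 4 times WT. Milder loss or degraded RNA stay open and untested.

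The 3 lists called higher in KO were set against 10000 random lists matched on abundance, in a family of 64 percentiles over 31 lists. Each gene of a random list was drawn independently, so a list whose genes move together can reach an extreme percentile. Immediate early genes lay at percentile 80.72 and basement membrane genes at 85.64, below the limit written before these percentiles were computed (the upper limit of a two-sided test at 0.05), so abundance alone may give such medians with 4 libraries, while without KO replicate 2 they lay at 99.41 and 87.0. YAP/TAZ targets lay at 97.6, under the uncalled cholesterol list (98.28), above the limit but within its sampling margin, a margin added after the value was seen, so abundance cannot be told apart from a list effect with 4 libraries. KO replicate 2 as the whole cause is argued against, since without it the list lay at 99.48, but 9 of 31 lists lay past either limit in that setting, with glycolysis (99.95) and contractile genes (99.86) further out, and the list's adjusted p there was 0.9585 with an estimated correlation. Without 5 members also induced as immediate early genes the remaining 15 lay at 95.82. By the limit written beforehand, this outcome went with stress of cell isolation. A condition added after the values were seen, a lower median without the 5, was not met (0.33 against 0.32) and left the question undecided. Of the 5, Ccn2, Gadd45b and Ankrd1 had log2 fold changes of 0.06, 0.03 and -0.57, and Ccn1 and F3 of 0.42 and 0.59. Leaving them out could hardly lower the median, so that condition tested little. Without KO replicate 2 the median was 0.07 for the 15 (percentile 82.25), against 0.18 for the 20 members tested with 4 libraries. Stress of cell isolation is not excluded and stays open. Loss of miR-205 stays open too, since the design cannot separate it from differences between the pooled cells of each genotype.

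All 7 tested members of the Serpina3 cluster, Serpina3n included, were lower in both KO libraries than in both WT libraries, at 110.4 and 172.9 CPM together in WT and 36.1 and 27.9 CPM in KO. The 6 members other than Serpina3n had 791 and 1336 counts together in WT and 89 and 0 in KO. The cluster was picked for its low level in KO, so neither reads of Serpina3n shared with its paralogs nor transcript loss in KO replicate 2 was tested, and differences between pools stay open.

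Luminal progenitor markers lay below nearly all matched random lists, at percentile 0.0 with 4 libraries and without KO replicate 2, among the same 64 percentiles. The genes of those random lists were drawn independently, while this list had an estimated correlation of 0.1933 with 4 libraries. Members that move together can give so low a percentile, so it does not measure how sure the difference is. Without KO replicate 2, milk genes (0.02), PI3K-AKT genes (0.14) and cell cycle genes (0.47) also lay below the lower limit. The camera adjusted p of the luminal progenitor list ran from 0.001067 without KO replicate 2 to 0.9612 without WT replicate 2, and was 0.8367 with an estimated correlation.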
